A study of Mus musculus with 4 samples.

How the data were processed

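RNA-seq was carried out on mouse cardiac fibroblasts, the stromal cells of the heart, that had been given the reprogramming factors Mef2c, Gata4 and Tbx5 (MGT) together with a short hairpin. One hairpin targets Nr4a3, an orphan nuclear receptor (shNr4a3), and the other is a non-targeting control (shNT). Per the labels, the cells were primary, wild type and from 3-month-old animals, were collected at reprogramming day 7, and gave 2 libraries per hairpin. The labels do not say that the 2 libraries of a group came from separate cultures or animals, so the p-values below measure only the spread between these samples, which may be technical.

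Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced in paired-end mode. The molecule label reads polyA RNA, which differs from the ribosomal depletion kit named in the protocol, and the conflict was left open. Per the submitters' processing notes, the tools named were Trimmomatic 0.36, SAMtools, and featureCounts of the Subread package 1.5.1, with the mouse build mm10. The aligner, the strand setting of the counting step and the annotation release are not given in the sources used here.

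The authors deposited raw read counts per gene, as whole numbers with no normalization, in 1 table with 1 column per library. The table used here holds 16383 genes on chromosomes 10 to 19, 1 to 5 and the first part of 6, where the last gene starts at position 70215400. The rest of chromosome 6 and chromosomes 7, 8, 9, X, Y and the mitochondrial genome were not analysed here. Column totals are therefore sums over the listed genes, not sequencing depth, and every normalised value is relative to these genes. They were 28220440 and 30479301 counts for shNT replicates 1 and 2, and 30395159 and 30976450 for shNr4a3 replicates 1 and 2. One count corresponded to 0.0323 to 0.0354 CPM. Exact intervals of count ratios and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Intervals of medians, and of a difference between medians, come from a bootstrap with 10000 draws. It resamples genes as if independent and does not cover spread between libraries.

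Gene symbols were used as deposited. Of these, 16048 (98.0%) were found on the same chromosome in GENCODE release M21 (GRCm38, equal to mm10), which gave coordinates, exon overlaps (bedtools 2.31.1) and GC content. Exons of 2553 genes overlap an exon of another gene of the table. The 22 genes of the gamma protocadherin cluster, which share their last exons, had close counts in 21 of 22 cases (2711 to 2961 in shNT replicate 1, with 6592 for Pcdhgc3), so reads in shared exons entered the count of each gene. With the strand setting not given, genes that overlap another gene on the opposite strand carry the same doubt. Among the genes named, Aspn overlaps Cenpp, Slc8a1 overlaps Gm11096, Gja5 overlaps Gpr89, C2 overlaps Zbtb12, Hmga1 overlaps AI413582, Ccne2 overlaps Ints8, Nusap1 overlaps Oip5, Ndufa4l2 overlaps Shmt2 and Ddit3 overlaps Mars on the opposite strand. On the same strand, S100a4 overlaps Gm42674, Ndufb8 overlaps Gm20538, and C2 and Cfb overlap Gm20547. Members of close gene families (Ifit, Ifi200, Oas, Serpina3, Phf11, H2, Myh, histone, granzyme, prolactin and Serpinb9 genes) can exchange reads with near-identical copies, and their values are uncertain to that extent.

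The libraries of each pair were first compared with each other. Over genes with at least 10 counts in the pair, the chi-square statistic divided by its degrees of freedom was 10.63 for shNT (11158 genes) and 22.14 for shNr4a3 (11092 genes). Both exceed counting noise, and all 4 libraries were kept as separate samples.

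Differential expression used the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, the hairpin as the only term, and Benjamini-Hochberg adjustment at 0.05. The filter kept 10736 genes, the TMM factors lay between 0.991 and 1.012, and the common dispersion was 0.00866. Values are normalised counts (CPM) after TMM scaling, as mean ± SD with n = 2 per group. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Where both libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with an exact (Clopper-Pearson) 95% interval.

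The 25 gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) where at least 5 members were tested, which left 23 lists, with Benjamini-Hochberg adjustment over them. Camera with an estimated correlation and the rotation test fry were run beside it. The lists were sarcomere, calcium and ion handling, cardiac regulators, fibroblast and matrix, myofibroblast and TGF-beta, senescence core, the senescence-associated secretory phenotype (SASP), p53 targets, G1/S, G2/M, NF-kB inflammation, interferon response, immediate early and Nr4a genes, oxidative phosphorylation, fatty acid oxidation, glycolysis and hypoxia, and the unfolded protein and integrated stress responses. A further set held markers of endothelial, macrophage, mural, skeletal muscle, mesothelial, Schwann, adipocyte and lymphocyte cells. These lists, the tests on them and the rule for named genes were fixed before the data were examined.

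That rule took Nr4a3 and the 3 factors, then the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold. Those genes needed a mean of at least 5 CPM in the higher group, no overlap between the groups, and a symbol that is not a predicted, clone or pseudogene name. From every list it took up to 4 members with the smallest p-values, or up to 2 from a list of another cell type. It named 105 genes. Genes outside the rule that the text names, among them Tnnt2, Myl4, Myl7, Acta2, Ctgf, Fn1, Pdgfra, Col1a1, Col3a1, Tgfbi, Hopx, Srf, Cdkn1a, Cdkn2a, Cdkn2b, Trp53, Il6, Cxcl1, Mdm2, E2f2, Tnfaip3, Ptgs2, Ifit3, Ifi27, Xaf1, Lyz2, Ddit3, Gja5, Chrna1 and Ndufa4l2, were chosen after their values were seen.

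Alternatives were RLE scaling, no low-count filter (at least 1 count in any library), a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out in turn. Library totals without TMM factors and the removal of genes with exon overlap were added after the data were seen. The fit was tested on simulated counts for the shNr4a3 and shNT comparison, in which 10586 genes passed the filter. It recovered 60.3% of 68 genes changed 1.5-fold, 69.7% of 66 changed 2-fold and 95.4% of 65 changed 4-fold. Of its calls, 7.45% were false. Only 200 changed genes were planted, whereas 60.2% of tested genes were called in the data. These rates depend on that share and cannot be carried over to the calls below.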

Results

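Gene expression was measured by RNA-seq in mouse cardiac fibroblasts undergoing direct reprogramming toward induced cardiomyocytes with Mef2c, Gata4 and Tbx5. The fibroblasts came from 3-month-old animals and were collected at reprogramming day 7. A hairpin against Nr4a3 (shNr4a3, 2 libraries) was compared with a non-targeting hairpin (shNT, 2 libraries) to ask, in the terms of the study's stated purpose, on what molecular basis loss of Nr4a3 enhances reprogramming. The libraries held 28220440 to 30976450 counts over the 16383 genes of the table, which covers 16 chromosomes, chromosome 6 only in part. Genes of chromosomes 7, 8, 9, X and Y were not analysed here. The share of counts taken by the 10 most abundant genes was 8.97% to 9.24% in shNT and 8.82% to 8.94% in shNr4a3. Histone genes took 0.0736% to 0.0761% of counts in shNT and 0.106% to 0.119% in shNr4a3. The 3 alpha haemoglobin genes held 0 to 6 counts per library, where 3 counts mark the floor. No mitochondrial or ribosomal RNA genes are among the rows analysed here.

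Nr4a3, the hairpin's target, fell in both knockdown libraries. The gene lies on chromosome 4 at 48045153 to 48086447 (mm10, plus strand, protein coding). It had 356 and 353 counts in the shNT libraries and 18 and 32 counts in the shNr4a3 libraries. This corresponds to 12 ± 0.648 CPM in shNT and 0.819 ± 0.315 CPM in shNr4a3 (mean ± SD, n = 2 each), a log2 fold change of -3.86 (SE 0.267, edgeR adjusted p = 2.65e-06). Reads of all 3 reprogramming factors, transcription factors of the developing heart that drive the conversion, were also lower under shNr4a3. Mef2c (chromosome 13, 83504034 to 83667080) went from 251 ± 20.6 to 168 ± 29 CPM (log2 fold change -0.58, SE 0.118, edgeR adjusted p = 0.00216). Gata4 (chromosome 14, 63198922 to 63271692) went from 182 ± 7.89 to 139 ± 10.1 CPM (log2 fold change -0.39, edgeR adjusted p = 0.00312). Tbx5 (chromosome 5, 119832668 to 119885219) went from 312 ± 33.5 to 239 ± 14.1 CPM (log2 fold change -0.39, edgeR adjusted p = 0.00572). The Tbx5 call was lost without shNT replicate 1 (log2 fold change -0.29, adjusted p = 0.0896). Reads from the delivered factor and from the endogenous gene cannot be told apart in these counts.

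**Figure D1:**
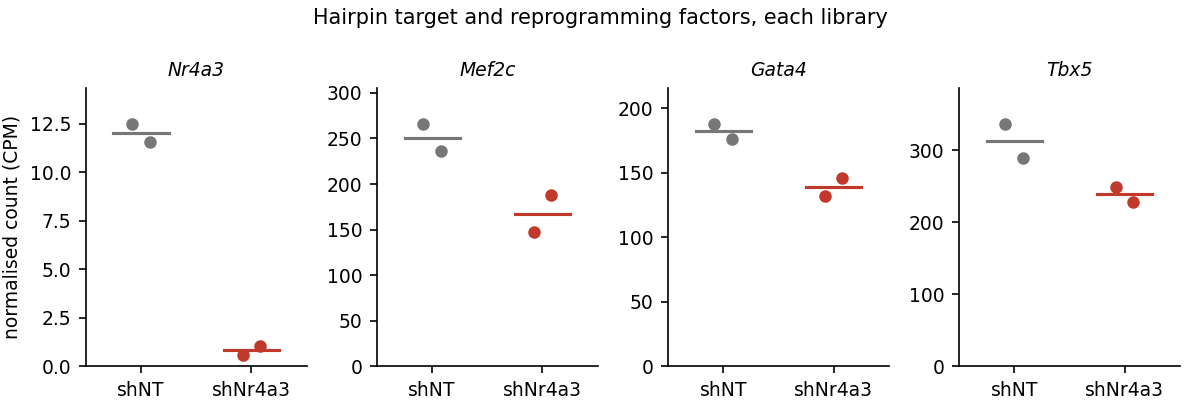
Normalised counts (CPM, linear axes from 0) of Nr4a3 and of the 3 reprogramming factors in each library, with points for libraries and a line for the mean of 2. Nr4a3 averaged 12 CPM in shNT and 0.819 CPM in shNr4a3, and the shNr4a3 libraries lay below both shNT libraries for each of the 4 genes.

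Expression differed widely between the hairpins. Of 10736 genes tested, 3300 were higher and 3158 lower in shNr4a3 (edgeR adjusted p under 0.05), 60.2% of all genes tested, and 2821 of them changed by more than 1 on the log2 scale (1383 higher, 1438 lower). The CPM of the groups did not overlap for 81.0% of tested genes, where chance gives 33.3%. The first principal component of log CPM separated the hairpins and held 88.5% of the variance. Among the genes with the largest rises, Stmn4, a microtubule-destabilising stathmin of neurons, went from 0.878 ± 0.0535 to 650 ± 27.4 CPM (log2 fold change 9.52, SE 0.126, edgeR adjusted p = 6.74e-10). Wnt16, a secreted Wnt ligand, rose from 0.472 ± 0.073 to 82.2 ± 1.35 CPM (log2 fold change 7.43). Sfrp4, a secreted Wnt antagonist, rose by 6.70 on the log2 scale to 24.9 ± 0.831 CPM. Aspn, the matrix proteoglycan asporin, went from 4.92 ± 0.912 to 422 ± 35.7 CPM (log2 fold change 6.42). Ptprz1, a receptor-type tyrosine phosphatase, rose by 6.51, Galnt16 by 6.40, Rec8, a meiotic cohesin subunit, by 6.29 and the transporter gene Slc6a18 by 6.81 on the log2 scale. Tmem196 and Pirt had only 2 counts in shNT, and their ratios were 362 (exact 95% interval 99.9 to 2995) and 146 (40.2 to 1214).

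Among the genes with the largest falls, Serpina3f, a serine protease inhibitor gene, had 144 and 154 counts in shNT and 0 in both shNr4a3 libraries, and was at least 104-fold lower. Igfbp5, a secreted binding protein for insulin-like growth factors, fell from 695 ± 55.8 to 18 ± 2.9 CPM (log2 fold change -5.27, SE 0.13, edgeR adjusted p = 1.70e-08). Ass1, the argininosuccinate synthase of the urea cycle, fell from 780 ± 93.6 to 30.8 ± 6.96 CPM (log2 fold change -4.66). Log2 fold changes were -5.95 for the interferon-inducible family member Ifit1bl1, -5.39 for Wdr66, -5.09 for both Pnma2 and Phf11a, -4.85 for the small GTPase Rem1, -4.66 for Ppl, the desmosomal protein periplakin, and -4.45 for Optc. The highest edgeR adjusted p among the 10 genes was 4.14e-05, for Phf11a.

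Genes of the cardiomyocyte contractile apparatus were mostly higher under shNr4a3. Of 24 sarcomere genes tested, 17 rose, 2 fell and 5 did not pass, with a median log2 fold change of 1.13. Adjusted over the list alone, the counts were also 17 and 2. Myoz2, a Z-disc protein, rose from 2.58 ± 0.219 to 37.3 ± 1.81 CPM (log2 fold change 3.85), and Actc1, cardiac alpha-actin, from 3.31 ± 0.518 to 43.3 ± 3.18 CPM (log2 fold change 3.71). The intermediate filament gene Des rose from 211 ± 43.8 to 1148 ± 49 CPM, and Ankrd1, a stretch-responsive titin-binding protein, from 3984 ± 219 to 11785 ± 444 CPM (log2 fold changes 2.44 and 1.56). Tnnt2, cardiac troponin T and the most abundant gene of the list in shNT, fell from 14209 ± 1562 to 7679 ± 790 CPM (log2 fold change -0.89, SE 0.103, edgeR adjusted p = 7.07e-05). The atrial light chain gene Myl7 fell by 0.37 on the log2 scale, and Myl4 had a log2 fold change of -0.14 (adjusted p = 0.16). The myosin heavy chain gene Myh6 passed as higher although its groups overlapped (4.027 and 2.585 CPM in shNT, 10.53 and 4.006 in shNr4a3, edgeR adjusted p = 0.0407). Myh7 was low in both groups and did not pass (1.71 ± 0.444 CPM in shNT and 1.41 ± 0.355 in shNr4a3). The list as a whole was higher in camera (adjusted p = 8.19e-07), but not with an estimated correlation (adjusted p = 0.42). Markers of skeletal muscle and of mural cells, which express some of these genes, went both ways in the same libraries (2 of 7 and 4 of 8 rose, 1 and 3 fell). Of all genes tested, 60.2% were called, so these counts alone do not show a change in those cells.

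Calcium and ion handling genes went both ways. Of 17 tested, 6 rose, 2 fell and 9 did not pass, with 5 and 2 adjusted over the list alone. The sarcoplasmic reticulum genes Trdn and Casq2 rose from 9.81 ± 1.43 to 141 ± 5.19 CPM and from 34.3 ± 5.98 to 265 ± 8.55 CPM (log2 fold changes 3.85 and 2.95), and the sodium-calcium exchanger Slc8a1 rose by 1.98 on the log2 scale. Jph2, which tethers the sarcoplasmic reticulum to the cell membrane, and the connexin gene Gja5 fell by 0.82 and 1.14. The camera adjusted p was 0.0351 upward and 0.623 with an estimated correlation, and the call was also lost with no low-count filter (0.0659), with limma-voom (0.218) and without genes that overlap another gene's exons (0.0583). Of 10 cardiac regulators and natriuretic peptides tested, 6 rose and 2 fell, as they did adjusted over the list alone. Nppa, atrial natriuretic peptide, rose from 2.97 ± 0.24 to 82.7 ± 3.66 CPM (log2 fold change 4.80, SE 0.123, edgeR adjusted p = 1.85e-08). Nppb rose by 2.58, and the transcription factor genes Hey2 and Prox1 by 3.11 and 2.59, while Srf and Hopx fell by 0.37 and 1.74. Camera gave an adjusted p of 0.00949 upward, 0.42 with an estimated correlation and 0.114 with limma-voom.

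**Figure D2:**
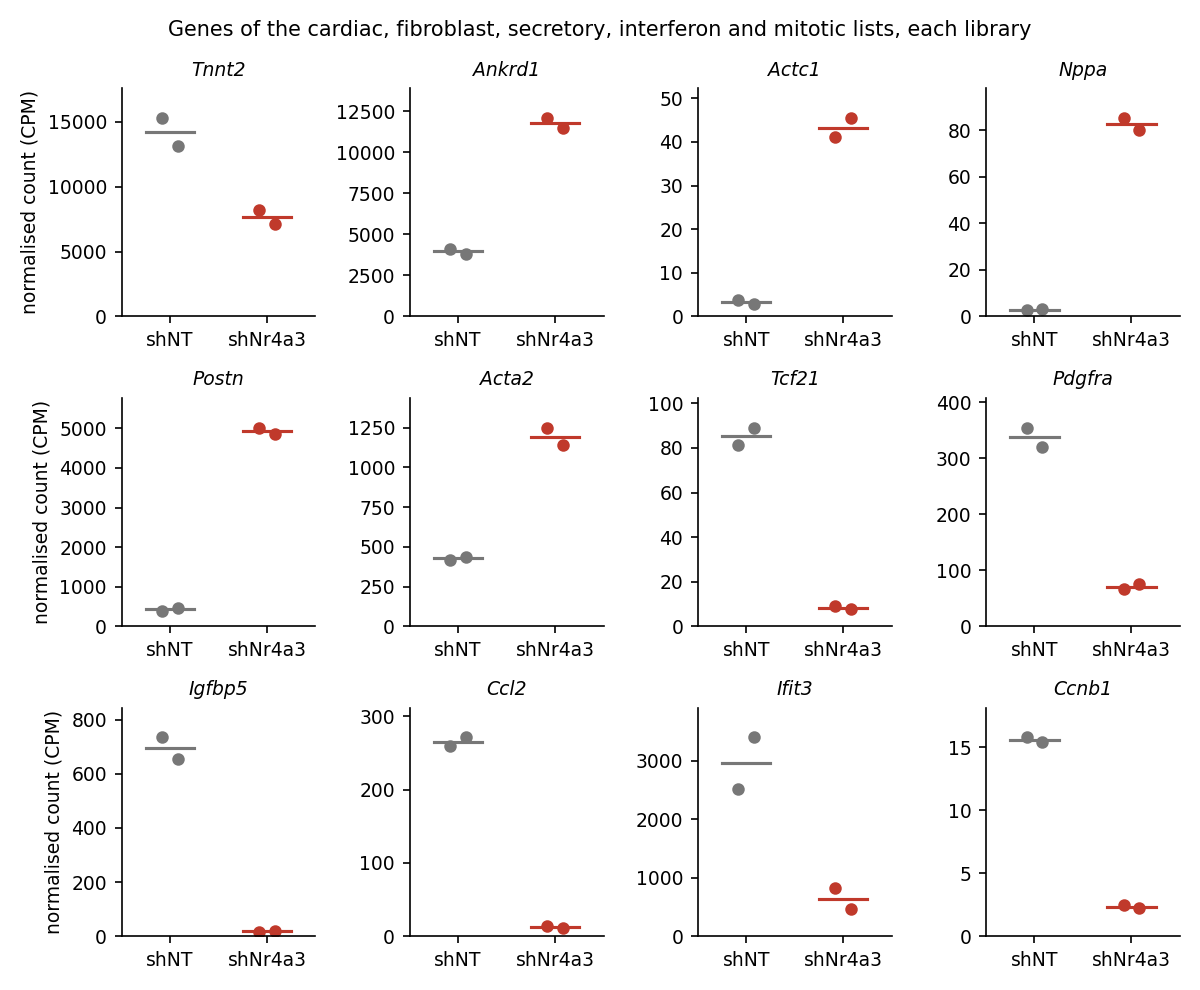
Normalised counts (CPM, linear axes from 0) of 12 genes in each library, with points for libraries and a line for the mean of 2. Ankrd1, Actc1, Nppa, Postn and Acta2 were higher in both shNr4a3 libraries, and Tnnt2, Tcf21, Pdgfra, Igfbp5, Ccl2, Ifit3 and Ccnb1 were lower.

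Fibroblast identity genes and matrix genes went both ways. Of 32 tested, 11 rose, 14 fell and 7 did not pass, and adjusted over the list alone the counts were also 11 and 14. Tcf21, a transcription factor of cardiac fibroblasts, fell from 85.3 ± 5.35 to 8.38 ± 1.17 CPM (log2 fold change -3.35), and Pdgfra, a surface receptor of these cells, from 338 ± 24 to 70.8 ± 5.8 CPM (log2 fold change -2.26). The metalloproteinase inhibitor Timp2 fell from 4423 ± 156 to 315 ± 53.5 CPM (log2 fold change -3.81), and S100a4 by 2.59 on the log2 scale. Postn, the matricellular protein periostin, rose from 429 ± 58.4 to 4941 ± 110 CPM (log2 fold change 3.53, SE 0.107, edgeR adjusted p = 3.85e-08), and Fn1, fibronectin, rose by 1.26. Col1a1 fell by 0.89, and Col3a1 had a log2 fold change of 0.01 (adjusted p = 0.876). The list did not pass in camera (adjusted p = 0.189).

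Genes of the myofibroblast state and of TGF-beta signalling were mostly higher, with 15 of 23 tested rising, 4 falling and 4 not passing (15 and 4 adjusted over the list alone). The camera adjusted p was 4.73e-05 upward and 0.42 with an estimated correlation. The ligand genes Tgfb3 and Tgfb2 rose from 221 ± 4.19 to 1761 ± 113 CPM and from 41.5 ± 1.56 to 255 ± 14.3 CPM (log2 fold changes 2.99 and 2.62). Cthrc1, a collagen triple helix protein of activated fibroblasts, rose by 2.37, the smooth muscle light chain Myl9 by 1.79, Acta2, smooth muscle alpha-actin, by 1.48 and Ctgf by 1.42. Tgfbi, a TGF-beta target, fell by 2.46 on the log2 scale. Markers of mural cells, which also express smooth muscle genes, went both ways in the same libraries (4 of 8 rose and 3 fell, where 60.2% of all genes tested were called).

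Core senescence genes did not shift in 1 direction. Of 22 tested, 6 rose, 8 fell and 8 did not pass (6 and 8 adjusted over the list alone), and camera gave an adjusted p of 0.476. The list mixes genes expected to rise in senescence with genes expected to fall. A test in 1 direction therefore cannot decide whether senescence changed. The genes that fell include Gata4, a delivered factor. The chromatin protein gene Hmga1 fell from 240 ± 7.53 to 52.8 ± 2.11 CPM (log2 fold change -2.18), and the cell cycle inhibitor Cdkn2c fell by 1.08. The damage-inducible genes Gadd45b and Gadd45a rose by 1.53 and 0.73. Cdkn2a, which encodes p16 and p19ARF, had 3.74 ± 0.802 CPM in shNT and 3.78 ± 0.324 in shNr4a3 (log2 fold change 0.02, SE 0.262, edgeR adjusted p = 0.962). Cdkn1a, which encodes p21, rose by 0.29, Cdkn2b rose by 0.88 and Trp53 fell by 0.56 on the log2 scale. Of 25 p53 targets, 14 rose and 5 fell (14 and 6 adjusted over the list alone), with Plk2 and Ak1 higher by 1.39 and 1.28, Bcl2l1 and Psrc1 lower by -1.33 and -1.30, and Mdm2 higher by 0.35. That list did not pass in camera (adjusted p = 0.349).

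Secreted factors of the senescence-associated phenotype, a list of cytokines, chemokines, growth factors and their binding proteins, were mostly lower. Of 37 tested, 6 rose, 23 fell and 8 did not pass, with a median log2 fold change of -1.35, and adjusted over the list alone the counts were also 6 and 23. Besides Igfbp5, the monocyte chemokine genes Ccl2 and Ccl7 fell from 265 ± 7.9 to 12.8 ± 1.8 CPM and from 149 ± 3.6 to 13.9 ± 3.44 CPM (log2 fold changes -4.37 and -3.43). Il6 fell by 1.55 and Cxcl1 by 1.91, while Vegfa, the endothelial growth factor, rose from 471 ± 32.9 to 1261 ± 13.7 CPM (log2 fold change 1.42). Camera gave an adjusted p of 9.06e-06 downward and 0.42 with an estimated correlation. Markers of macrophages, which also express many of these chemokines, were in part lower in the same libraries (8 of 17 fell).

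Cell cycle genes were mostly lower. Of 28 G2/M genes tested, 25 fell, 0 rose and 3 did not pass (26 fell adjusted over the list alone). Ccnb1, the mitotic cyclin B1, fell from 15.6 ± 0.248 to 2.33 ± 0.167 CPM (log2 fold change -2.74, SE 0.174, edgeR adjusted p = 1.59e-06), the spindle motor Kif11 by 2.24, Nusap1 by 1.93 and the kinetochore protein Cenpf by 1.64. Of 30 G1/S genes, 21 fell, 1 rose and 8 did not pass, as they did adjusted over the list alone. The histone mRNA binding protein Slbp fell by 1.02, the replicative helicase subunit Mcm6 by 1.04, Ccne2 by 0.76 and Uhrf1 by 0.86. The gene that rose was E2f2, from 2 counts over both shNT libraries to 25 and 20 counts. E2f2 had too few shNT counts to enter the test without shNr4a3, so the filter favoured its call. The camera adjusted p was 1.88e-07 downward for G2/M and 0.0374 for G1/S, and 0.42 and 0.723 with an estimated correlation. The G1/S call was also lost without shNr4a3 replicate 2 (adjusted p = 0.0797) and without genes that overlap another gene's exons (0.0542).

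Interferon response genes fell nearly as a block. Of 33 tested, 31 fell, 1 rose and 1 did not pass, with a median log2 fold change of -1.83 and the same counts adjusted over the list alone. Zbp1, a nucleic acid sensor, fell from 195 ± 24.9 to 10.2 ± 2.26 CPM (log2 fold change -4.26, SE 0.156, edgeR adjusted p = 9.26e-08). Parp14 fell from 544 ± 97.9 to 46.8 ± 7.69 CPM, Oas2 by 3.60 and Ifi204 by 2.87 on the log2 scale. Ifit3, the list's most abundant gene in shNT, fell from 2954 ± 627 to 638 ± 253 CPM. Ifi27 rose by 1.28, and Xaf1 had a log2 fold change of -0.06 (adjusted p = 0.617). Camera gave an adjusted p of 8.91e-15 downward, and an adjusted p of 0.623 with an estimated correlation, which was 0.834 for this list. Of the 17 macrophage markers, 8 were lower in the same libraries. Of 23 NF-kB and inflammation genes, 13 fell, 2 rose and 8 did not pass (13 and 2 adjusted over the list alone). Vcam1, an adhesion molecule for leukocytes, fell from 502 ± 21.4 to 97.4 ± 9.77 CPM (log2 fold change -2.37), Tnfaip2 by 2.20, complement C3 by 2.19 and the interleukin-1 receptor Il1r1 by 2.55. The genes that rose were Tnfaip3, an inhibitor of NF-kB signalling (log2 fold change 1.87), and Ptgs2 (1.02). Camera gave an adjusted p of 2.97e-04 downward and 0.42 with an estimated correlation.

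**Figure D3:**
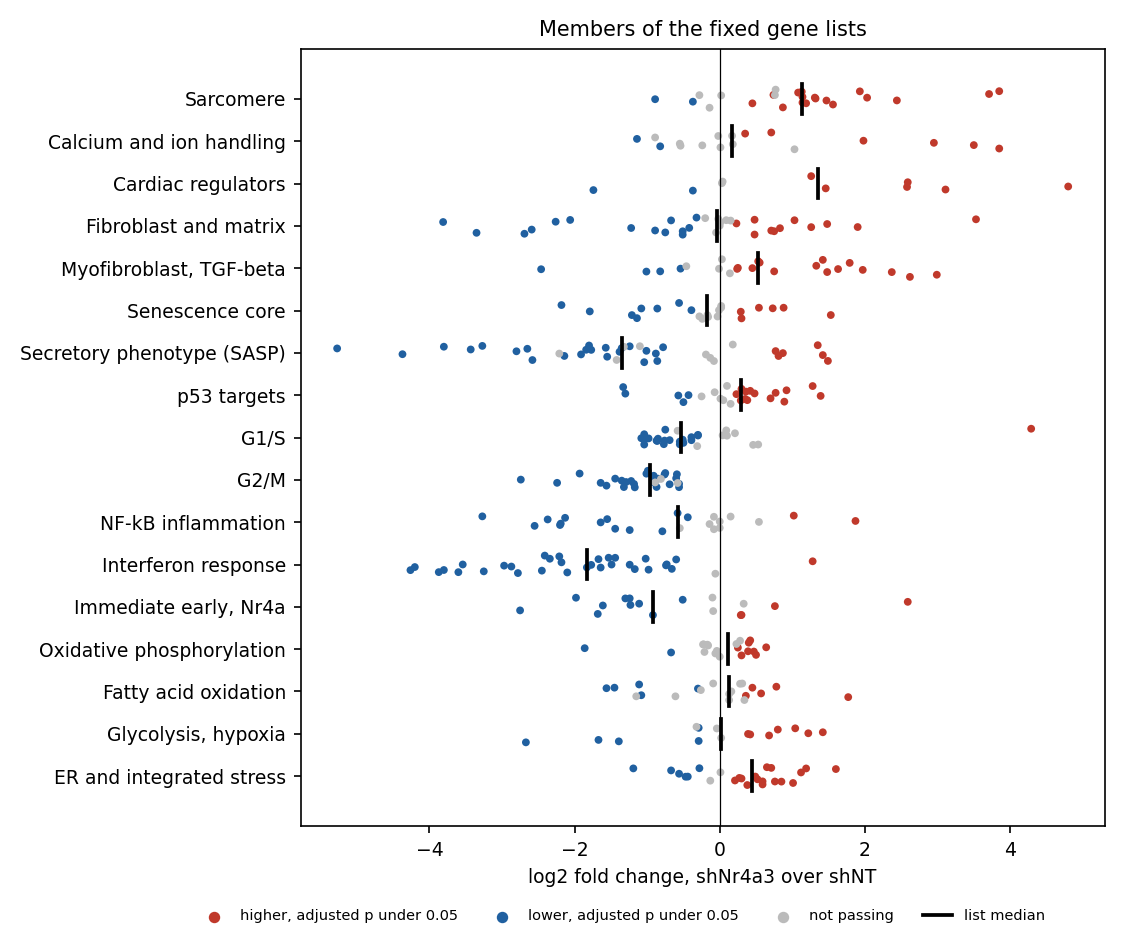
Log2 fold changes (shNr4a3 over shNT, horizontal axis) of every tested member of the 17 lists of cell programmes (vertical axis), coloured by whether the gene passed at an adjusted p under 0.05, with the list median as a bar. Medians were 1.13 for sarcomere, -1.35 for secreted senescence factors, -0.96 for G2/M and -1.83 for interferon response genes.

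Immediate early genes and the other Nr4a receptors also moved. Of 17 tested, 10 fell, 4 rose and 3 did not pass (10 and 5 adjusted over the list alone). Nr4a1, a paralogue of the target, fell from 43 ± 7.19 to 6.41 ± 0.68 CPM (log2 fold change -2.75, SE 0.153, edgeR adjusted p = 7.51e-07), whereas Nr4a2, the other paralogue, rose from 2.49 ± 0.359 to 15.1 ± 1.33 CPM (log2 fold change 2.59). The transcription factor genes Klf4 and Egr1 fell by 1.98 and 1.68. Camera gave an adjusted p of 0.00949 downward, 0.707 with an estimated correlation, and 0.0525 without the genes that overlap another gene's exons.

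Metabolic lists did not pass in camera. Of 20 oxidative phosphorylation genes from the nuclear genome, 8 rose and 2 fell (the same adjusted over the list alone), with Sdha, a subunit of succinate dehydrogenase, falling from 353 ± 4.27 to 97.6 ± 4.51 CPM (log2 fold change -1.86), Atp5b falling by 0.67, and Ndufb8 and Ndufa4 rising by 0.47 and 0.50 (list adjusted p = 0.886). Of 20 fatty acid oxidation genes, 5 rose and 5 fell (4 and 4 adjusted over the list alone), with Cpt1a, the mitochondrial fatty acid importer, falling by 1.08, Acaa2 by 1.45, Cd36 by 1.56 and Hadh by 1.11 (list adjusted p = 0.684). The medians of these 2 lists were 0.11 and 0.13, above 0, while camera placed both downward. Of 15 glycolysis and hypoxia genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone), with P4ha1 and Pgam1 higher by 1.22 and 0.80 and Ndrg1 lower by -2.67 (list adjusted p = 0.727). In the unfolded protein and integrated stress responses, 16 of 24 genes rose and 6 fell (the same adjusted over the list alone). The serine and asparagine synthesis genes Phgdh, Psat1 and Asns rose by 1.12, 1.60 and 1.19, the chaperone Dnajb9 rose by 0.85, and Ddit3 fell by 0.47. The list did not pass in camera (adjusted p = 0.104), and it passed with limma-voom (adjusted p = 0.0456), with no low-count filter (0.0297) and without shNr4a3 replicate 2 (0.0484).

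Markers of other cell types that a heart fibroblast culture can hold were read as a check on composition, and none of these lists passed in camera. Among 17 macrophage genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with Cd68 going from 21.3 ± 2 to 6.95 ± 0.617 CPM and Mpeg1 from 24.7 ± 4.03 to 10.3 ± 0.309 CPM. Lyz2, the most abundant macrophage gene tested, had 152 ± 25.2 and 135 ± 3.3 CPM (log2 fold change -0.17, adjusted p = 0.208). The macrophage list had a camera adjusted p of 0.113, which became 0.0286 with no low-count filter, 0.0419 with limma-voom and 0.0141 without shNT replicate 2, all downward. Of 13 endothelial genes, 2 rose and 4 fell (2 and 2 adjusted over the list alone), with Ptprb and Tek lower by -0.82 and -0.81. That list had an adjusted p of 0.886 and a median of 0.23, opposite to camera's direction. Of 8 mural genes, 4 rose and 3 fell, in total and adjusted over the list alone, with Notch3 and Myh11 higher by 1.27 and 1.43 (list adjusted p = 0.505). Ndufa4l2, with 0 counts in both shNr4a3 libraries, was at least 35.5-fold lower. Of 7 skeletal muscle genes, 2 rose and 1 fell, also adjusted over the list alone. The myosin heavy chains Myh1 and Myh2 were higher by 1.21 and 1.09, and Chrna1 was lower by -2.13 (list adjusted p = 0.357). Of 10 mesothelial genes, 4 rose and 2 fell, also adjusted over the list alone, with Sema3d rising from 178 ± 0.933 to 551 ± 1.4 CPM and Msln falling from 29.8 ± 7.6 to 4.57 ± 0.565 CPM (list adjusted p = 0.824). Of 6 Schwann cell genes, 2 fell (Egr2 by 1.61 and Cdh19 by 1.35) and 0 rose, also adjusted over the list alone (list adjusted p = 0.425). The adipocyte and lymphocyte lists had only 2 and 1 tested members and no list test. Fabp4 was higher by 0.54 (adjusted p = 0.0456), a call lost in 5 of the alternatives, Plin4 had a log2 fold change of -0.75 (adjusted p = 0.088), and Lck fell from 0.764 ± 0.108 to 0.082 ± 0.0222 CPM.

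The comparison rests on 2 libraries per hairpin, and with 2 against 2 an exact permutation test of a single gene cannot go below p = 0.333. A hairpin and its target are not separable here, because the labels name 1 hairpin per group.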

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

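Library totals alone and the removal of genes with exon overlap were chosen after the data were seen, and the other alternatives before. Where edgeR with TMM scaling called 3300 genes higher and 3158 lower, the totals called with other settings were as follows: RLE scaling 3275 and 3238, no low-count filter 3247 and 3185, a mean of at least 5 CPM 2714 and 2602, DESeq2 2986 and 2915, limma-voom 3335 and 3191, library totals alone 3215 and 3258, and genes without exon overlap 2623 and 2534. DESeq2 shared 90.4% of the edgeR calls in the same direction. Leaving out 1 library gave 2680 to 3263 higher and 2565 to 3180 lower genes, with the lone sample of a group assumed to vary like the other group. The count with an absolute log2 fold change over 1 went from 2821 to 1775 at a mean of at least 5 CPM, where only 7939 genes were tested. The share of higher calls stayed within 49.5% to 51.3% and the median log2 fold change within -0.008 to 0.018 in these alternatives. Replicate numbers did not pair the samples (correlation of deviations 0.023), and the replicate block gave 3404 higher and 3255 lower genes and changed no call of a list or a named gene. The log2 fold change of Nr4a3 ranged from -4.33 to -3.52 without 1 library, and that of Tbx5 from -0.49 to -0.29, with its call lost without shNT replicate 1. Of the 105 named genes, Fabp4 and Tbx5 were the only ones to lose a call in any alternative that tested them, and none changed direction. With no filter the list test for calcium handling gave an adjusted p of 0.0659, stress responses 0.0297 and macrophages 0.0286, and oxidative phosphorylation turned upward (0.864). With limma-voom these were 0.218, 0.0456, 0.0419 and 0.707, again upward, and cardiac regulators 0.114. Estimated correlation ended all 10 list calls, with adjusted p of 0.42 for sarcomere, cardiac regulators, myofibroblast, SASP, G2/M and NF-kB, 0.623 for calcium handling and interferon, 0.707 for immediate early genes and 0.723 for G1/S. With 2 residual degrees of freedom that correlation is poorly determined, and the unadjusted p was under 0.05 for 2 lists. The fry test, which does not compare a list with other genes, added p53 targets (0.0456), stress responses (0.0292) and skeletal muscle (0.0448). Genes without exon overlap gave 0.0583 for calcium handling, 0.0542 for G1/S and 0.0525 for immediate early genes. Without 1 library, adjusted p ranged from 0.0202 to 0.0797 for G1/S, 0.0484 to 0.164 for stress responses, 0.0141 to 0.294 for macrophages, 0.638 to 0.948 for oxidative phosphorylation, 0.818 to 0.924 for endothelial and 0.706 to 0.96 for mesothelial markers, and the last 3 turned direction in 1 case each (0.818 without shNr4a3 replicate 2, 0.924 and 0.96 without shNT replicate 2). The causes were not tested. Shares without mitochondrial genes were not run, because 0 such genes are among the rows analysed here. Depth limits the genes near 3 counts per group, for which only bounds or wide intervals are given.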

Other observations

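The gene groups of the next 2 paragraphs were chosen after the data were seen, as were the tests on macrophages, S phase, factor RNA and the share of abundant genes further on, and no list test is given for these groups. Genes that present antigen on MHC class I fell together in shNr4a3, with 15 of 17 lower, 0 higher and 2 not passing (edgeR adjusted p under 0.05). H2-K1, a class I heavy chain, went from 1296 ± 66.6 to 86.7 ± 10 CPM (mean ± SD, n = 2 each, log2 fold change -3.90), the immunoproteasome subunit Psmb8 from 103 ± 11.4 to 5.92 ± 1.84 CPM (log2 fold change -4.12), and B2m fell by 0.62. Complement genes split, with 6 of 11 lower and 3 higher. Cfb and C2 fell by 4.30 and 3.92 on the log2 scale, whereas Masp1, a protease of the lectin pathway, rose from 5.2 ± 0.276 to 53.8 ± 2.36 CPM. Macrophages also express antigen presentation and complement genes, and 8 of 17 macrophage markers fell in the same libraries (median -0.96), so a part of these falls can come from a change in cell composition.

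Of 25 secreted Wnt pathway genes in the table, 13 were tested, of which 8 were higher and 3 lower. Sfrp4 and Rspo2 entered the test on shNr4a3 counts alone, and Rspo1 and Wnt4 on shNT counts alone, so the filter favoured their calls. Besides Wnt16 and Sfrp4, Wnt5a rose from 8.96 ± 1.03 to 56.2 ± 2.02 CPM, while Rspo1, an R-spondin, fell by 4.32 on the log2 scale. Class 3 semaphorins and their receptors had 5 of 8 higher and 2 lower, with Sema3a and Sema3c up by 3.11 and 2.40 and the receptor Nrp2 down by -1.38. All 22 gamma protocadherin genes were higher, with a median log2 fold change of 1.74, but their shared last exons make this close to 1 measurement of the locus. In the Serpinb9, granzyme and prolactin families, whose members in mouse are known for expression in placenta and cytotoxic lymphocytes, only 13 of 41 genes in the table were tested, of which 11 were higher and 1 was lower. The filter admits a gene on the counts of either group. Of the 13, 5 had 0 counts in shNT and entered on shNr4a3 counts alone. Gzmc, Prl2c3, Prl8a9, Prl7a1 and Prl2c2 also had too few shNT counts to enter without shNr4a3. For all of these a higher call was largely set by the filter, and so were the count of 11 and the median. Serpinb9b, Serpinb9 and Gzmm, which shNT counts could admit, had log2 fold changes of 0.39 (higher), -1.36 (lower) and 0.25 (not passing). Serpinb9c and Serpinb9g had 0 counts in both shNT libraries and were at least 65-fold and 29.3-fold higher, Gzmc rose from 2 counts in each shNT library to 129 and 130 counts, and Serpinb9 itself fell by 1.36. The median log2 fold change was 4.70 as fitted and 3.88 with the 5 genes absent from shNT at their bounds, and near-identical copies leave single members uncertain.

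Interferon response genes fell by a median of 1.83 on the log2 scale. Fewer macrophages in the knockdown would lower macrophage markers at least as much. The 17 such markers had a median of -0.96, which is 0.87 above that of the 33 interferon genes (bootstrap 95% interval 0.30 to 1.63). That interval resamples genes as if independent, but the estimated inter-gene correlation was 0.834 for interferon and 0.737 for macrophage genes. It does not cover spread between libraries, so only the medians are compared here. Lyz2, the most abundant marker, stood at 152 and 135 CPM. Other markers did fall, Cd68 by 1.61 and Mpeg1 by 1.26, with 8 of 17 lower and 1 higher. A bias with GC content or gene length was argued against, since the median stayed at -1.77 (interval -2.40 to -1.44) once that trend was removed. What stays open is how far a loss of macrophages contributes. It also stays open whether the fall follows from the loss of Nr4a3 or from a stronger response to the control hairpin or its vector, because no library without a hairpin was analysed here.

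Of 48 histone genes tested, 20 rose, 0 fell and 28 did not pass, with a median log2 fold change of 0.89, while 21 of 30 G1/S genes fell, a list call lost with an estimated correlation (adjusted p = 0.723), without shNr4a3 replicate 2 (0.0797) and without genes that overlap another gene's exons (0.0542). Length and GC bias would raise matched genes, but 247 non-histone genes of like length and GC content had a median of -0.10 (interval -0.20 to 0.08). Reads shuffled between near-identical histone genes would leave their sum alone if each read was counted once. Yet the summed histone CPM rose by 0.61 on the log2 scale, from 734 and 752 in shNT to 1066 and 1196 in shNr4a3. How reads that match several genes were counted is not given. Reads dropped or counted more than once could change the sum, and the sum cannot exclude that. More cells in S phase as the only change would raise the G1/S genes, whereas they fell (median -0.53, bootstrap 95% interval -0.75 to -0.35). That fall is part of the pattern and is no separate test. It cannot tell whether a rise in S phase cells was offset by another change. Polyadenylated histone transcripts of cells that leave the cycle stay open, as does a difference in how much non-polyadenylated RNA each library kept, and neither was tested.

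Tnnt2 fell by 0.89 on the log2 scale while most sarcomere genes rose. The planned test left the 10 most abundant genes of each library out of the scaling. It gave Tnnt2 a log2 fold change of -0.89, but could not decide, because these genes hold too few counts to undo the fall. A different share of counts in a few abundant genes was examined through the share outside the 14 genes that rank among the 10 most abundant of any library. That share had a log2 ratio of 0 between the groups (-0.001 to 0.002 over pairs of libraries). The groups did not differ in it, so a shift of counts into these 14 genes does not account for the fall. The similar shares of the 10 most abundant genes given above had already shown this, so it is no separate test. Less factor RNA as the only change would lower the sarcomere genes as a set, whereas the 23 others rose (median 1.14, bootstrap 95% interval 0.76 to 1.32). That rise is part of the pattern and is no separate test. It cannot tell whether a lowering by less factor RNA was outweighed. Whether lower factor RNA acts on Tnnt2 or on the other sarcomere genes stays open, because factor RNA and the hairpin changed together in these 4 libraries.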
